A study of Sus scrofa with 16 samples.

How the data were processed

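The samples were lymph node and lung RNA of infected pigs, with an RNA integrity number above 8.5 per the labels' protocols, amplified and labelled with 2 dyes. Each array paired 1 sample with a pooled reference. The values are log ratios of the 2 channels of each spot, deposited by the authors in a table of the whole series, and are taken as log2. The base of the logarithm, the background correction and the normalization are not given in the sources used here, and a differing base would rescale all values alike. The authors' processing left the array medians within 0.0097 of 0, so the ratios are centred. Scanner intensities were not used here, so that no probe was left out for low signal. Values of arrays with the sample in Cy3 are written with up to 10 significant digits and those with it in Cy5 with at most 6. The orientations may thus have been written by different steps, which was not tested. Probes were named through the annotation of the platform: 178 probes had 1 symbol, 0 had several and 20558 had none. All 178 matched the RefSeq table of Sscrofa11.1 by gene number, which changed 0 symbols. CD163, which was to be reported in any case, is on none of the named probes. No coordinates are given, since the array's build is not named.

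The labels do not say whether a value is channel 2 over channel 1, sample over reference or reference over sample. The first was set against the others without the burden groups, from correlations between arrays of the same and of opposite orientation. A second planned check, on the mean ratio of variable probes, decides nothing: it assumed a pool of the samples themselves, and turning 4 of 8 arrays that share a departure from the reference moves their mean toward 0 under either reading. The difference between the tissues, in which a dye bias shared by both tissues cancels, was compared between orientations after the data had been examined. Without that comparison the fixed design would have fallen back on channel 2 over channel 1, had the correlations been held not to settle it. It would then have written no direction, so the directions given here go with the assumed reading alone. The correlations leave sample over reference and its uniform inverse equal, and sample over reference was assumed. Channel 2 over channel 1 is an alternative, and the uniform inverse only turns every sign. The design had assumed that each tissue had a pool of its own samples as reference, so that its samples would scatter about 0. The samples instead share large departures from the reference, with a median correlation of 0.538 between lymph node and lung arrays. The reference carries 1 name on all lymph node arrays, and in lung a name of its own on the low burden Cy3 arrays, on the high burden Cy3 arrays and on all Cy5 arrays.

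High and low burden were compared in each tissue alone (8 arrays) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with dye orientation as a term and Benjamini-Hochberg adjustment over all probes, at an adjusted p of 0.05. A probe needed a value on at least 3 arrays of each group. The difference between tissues came from 1 fit over all 16 arrays with the 4 groups and dye orientation within each tissue. Gene lists were tested with camera at a preset correlation of 0.01 on genes, the probes of a symbol averaged. These tests, the lists and the rule for named genes were fixed before the data were examined. The rule took, per tissue, the 10 largest rises and the 10 largest falls among named probes past the threshold whose 4 high arrays lay on one side of the low mean, filled to 10 by the smallest unadjusted p and then given as values. For the difference between tissues it took 5 per direction, for a list past the threshold the 4 members with the smallest unadjusted p in its direction, and SIGLEC1 and CD163 in any case. The 5 called lung probes have no symbol, fall outside this rule and were named by number after their values were seen. The labels do not say which lung and which lymph node came from 1 pig, nor that the samples of a group came from separate animals, so samples were not paired and p-values measure only the spread between these samples, which may be technical.

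The probes form 48 blocks, and each array block was compared with the same block of the other arrays at shifts of up to 3 spots. Of 768 array blocks, 15 on 5 arrays (1.95% of all values) had a correlation below 0.3 in place and above 0.5 after a shift of 1 or 2 spots, and are called misplaced. All 40 shifts put into the data on purpose were found with the right size. The values were kept as deposited in the main results, with these blocks left out or moved back as alternatives. On simulated data with independent noise and 200 probes changed at once, limma recovered in lung 91% of changes of 1 and 100% of changes of 2 on the log2 scale. There were 12 false calls among 20736 probes, and 11 in lymph node. A list of 3 genes shifted by 3, more than the burden difference of any list member here, was found among 175 genes with no other list past the threshold.

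Alternatives were the other reading of the ratio, no dye term, centring, scaling, quantile normalization, filters on missing values and on spread, array weights, robust moderation, other thresholds, genes in place of probes, 1 fit over all arrays, each orientation alone, fry and an estimated correlation for the lists, and leaving out each array. The misplaced blocks, the print positions and the print set were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the block comparison and the plots.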

Results

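Gene expression was measured in the bronchial lymph nodes and lungs of Hampshire by Duroc cross pigs infected through the nose with porcine reproductive and respiratory syndrome virus (PRRSV), an arterivirus that replicates in macrophages. The tissues were taken on day 14. Pigs with a high and pigs with a low virus burden were compared, with 4 samples per group in each tissue and 16 arrays in all. Each sample was hybridised with a pooled reference RNA to a 2-colour array of 20736 probes, and 2 arrays of each group carried the sample in Cy5 and 2 in Cy3. Every probe had a value on every array, and the array medians lay within 0.01 of 0. Gene symbols were at hand for 178 probes (175 genes), and the other 20558 probes are given here by number only. The number of arrays limits the precision, and the p-values measure the spread between these samples.

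Relative to the reference, the lymph nodes held more RNA of PSMB8, PSME1 and TLR10, and both tissues less of CRP and PROC. PSMB8, a catalytic subunit of the immunoproteasome, lay at 0.87 ± 0.41 (SD, n = 8), the proteasome activator subunit PSME1 at 0.62 ± 0.15, the Toll-like receptor TLR10 at 0.67 ± 0.24, the monocyte lectin FCN1 at 0.97 ± 0.49 and TYROBP, the adaptor of activating receptors on myeloid and NK cells, at 0.50 ± 0.31, all as log2 of sample over reference. CRP, an acute phase protein made by the liver, lay at -3.14 ± 0.43, protein C (PROC) at -2.99 ± 0.22, INHA at -1.50 ± 0.38 and urate oxidase (UOX) at -1.44 ± 0.32. In the lungs, the pancreatic-type phospholipase PLA2G1B lay at 1.38 ± 0.57, S100A11 at 1.22 ± 0.17, the mitochondrial translocator protein TSPO at 1.17 ± 0.25 and JUN at 0.75 ± 0.79, while CRP lay at -2.48 ± 0.58 and PROC at -2.05 ± 0.93. In limma's test against 0, added after the values had been seen, 17 named probes were above and 33 below the reference in lymph node at an adjusted p under 0.05, and 17 above and 11 below it in lung. PSMB8 was read from misplaced spots on 1 array of each tissue, and without them lay at 0.99 in lymph node and 0.34 in lung. JUN was so on 2 lung arrays (1.03 without them) and PROC on 1 (-2.34 without it).

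**Figure D1:**
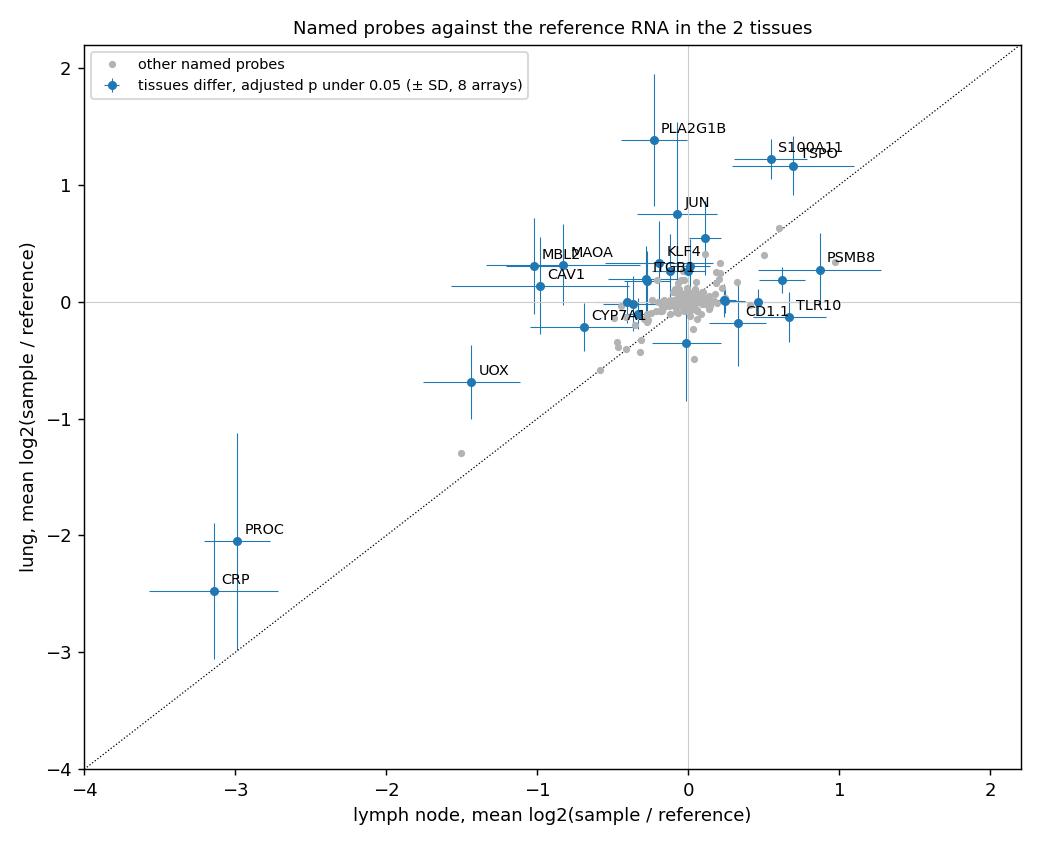
Mean log2 ratio of sample over reference of the 178 named probes in lymph node (x axis) and lung (y axis), 8 arrays each. Coloured points, with SD bars, are the 8 probes higher and the 21 lower in lymph node than in lung at an adjusted p under 0.05, and the dotted line marks equal values. CRP and PROC lie farthest below 0 in both tissues, and PLA2G1B lies highest in lung.

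The direction of the ratio is not given by the labels and was taken as sample over reference on all arrays. Arrays of opposite dye orientation correlated as closely (median r across probes 0.773 in lymph node and 0.665 in lung) as arrays of the same orientation (0.772 and 0.688). The difference between lymph node and lung had the same direction in both orientations, with r = 0.703 across probes, which are not independent replicates, a comparison made after the data had been seen. These correlations speak only against channel 2 over channel 1, since they would be the same if every value were reference over sample. The high minus low difference, with the print positions left out, correlated between orientations at r = -0.05 in lymph node and 0.29 in lung. In lymph node the burden differences thus did not recur between orientations, each with 2 arrays per group. That sample stands over reference is an assumption, and the inverse would turn the sign of every level and difference given here and leave the number of calls as it is. Under the assumption, the lymph node minus lung difference was 0.80 for TLR10, known from B cells, and -1.12 for CAV1, abundant in lung (-1.36 without its 1 misplaced array), both picked after the values had been seen.

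The lymph nodes of high and low burden pigs were compared to ask which genes accompany the virus load at the site that drains the lung. No gene passed the test, and the named genes are given as values. The high minus low difference of the T cell chemokine receptor CXCR6 was 0.30 ± 0.10 on the log2 scale (SE, 4 arrays per group), that of the calcium channel subunit CACNB4 0.29 ± 0.09, that of FCN1 0.59 ± 0.24 and that of CYP7A1, the rate-limiting enzyme of bile acid synthesis, 0.39 ± 0.16. It was 0.24 ± 0.11 for the transcription factor GATA6 and 0.27 ± 0.12 for the mucosal addressin MADCAM1. The remaining positive values were those of CRSP3, UOX, the somatostatin receptor SSTR2 and the glycine receptor subunit GLRB, between 0.15 and 0.34. On the negative side, TYROBP had a difference of -0.36 ± 0.15, with group means of 0.68 ± 0.32 (SD, n = 4) in low and 0.32 ± 0.17 in high burden pigs. The neutrophil granule protein PGLYRP1 had -0.71 ± 0.33 and the glycosyltransferase B3GNT5 -0.51 ± 0.34, and both rest on 1 array: without high burden lymph node replicate 1 the differences were -0.32 and -0.10. Lymphotoxin alpha (LTA), read from misplaced spots on 1 of these arrays, had -0.16 ± 0.08. GNAS, tissue kallikrein (KLK1), CA11, MYH7, the folate receptor FOLR1 and MYOCD had differences between -0.37 and -0.12. SIGLEC1 (sialoadhesin), a macrophage receptor to which PRRSV attaches, had 0.02 ± 0.07. The adjusted p was 0.956 for each of these genes except SIGLEC1, for which it was 0.985.

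Over all 20736 probes of the lymph node comparison, 0 passed an adjusted p of 0.05 in limma's test, and the smallest adjusted p was 0.377. An unadjusted p under 0.05 was reached by 857 probes, where 1037 would be expected by chance. Among named genes, 5 of 178 probes had an unadjusted p under 0.05 and 0 passed an adjusted p of 0.05 over the named probes alone (smallest 0.850). In simulated data with the spread of these arrays and independent noise, 100 probes changed by 1 on the log2 scale and 100 by 2, all at once. Of these, 93% and 99% were recovered. The adjustment is less strict when many probes change together, and a single changed probe was not simulated. These shares thus do not tell whether a change of 1 in a few probes would have passed here. With 1 array left out at a time, the value of FCN1 went down to 0.35, those of GATA6 and MADCAM1 to 0.14 and 0.17, and those of TYROBP, KLK1 and FOLR1 came up to -0.24, -0.08 and -0.08. Those of GNAS, CA11 and MYOCD came up to -0.15, -0.09 and -0.06.

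**Figure D2:**
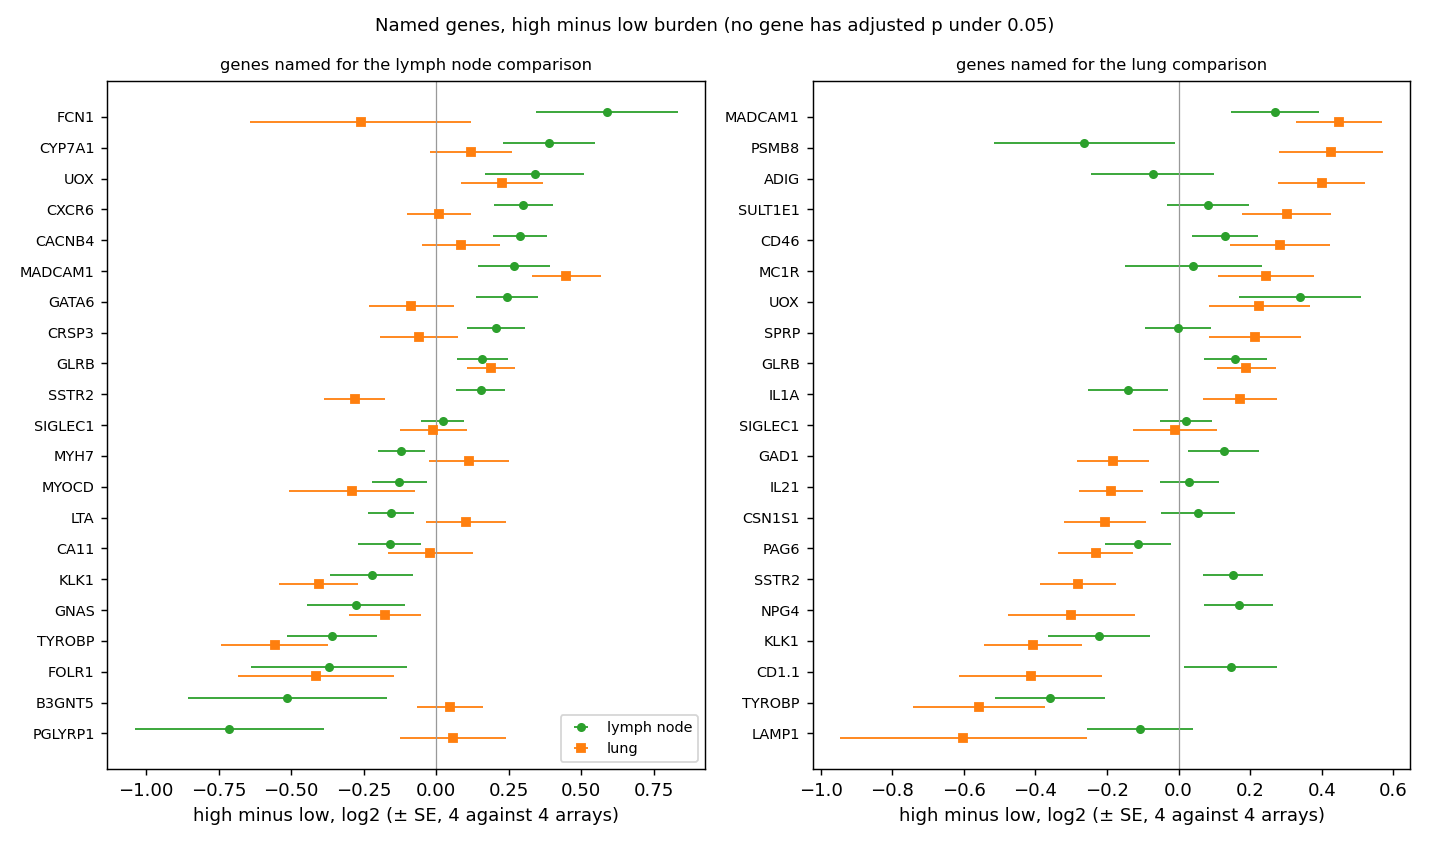
High minus low burden difference on the log2 scale (x axis), with SE, of the genes named for the lymph node (left) and for the lung (right), each shown in both tissues. No gene had an adjusted p under 0.05. TYROBP lies below 0 and MADCAM1 above 0 in both tissues.

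In lung, 5 probes passed an adjusted p of 0.05 in limma's test, 2 higher and 3 lower in high burden pigs, and no symbol was at hand for any of them. Probe 8267 fell by 3.38 ± 0.23 on the log2 scale (SE, adjusted p = 0.00288), from -0.37 ± 0.39 (SD, n = 4) in low to -3.75 ± 0.65 in high burden lungs. Probe 4956 fell by 3.86 ± 0.36 (adjusted p = 0.0146), from -0.82 ± 0.44 to -4.68 ± 0.79. Probe 14467 fell by 1.07 ± 0.11 (adjusted p = 0.0218), from 1.12 ± 0.10 to 0.05 ± 0.18. Probe 7068 rose by 1.25 ± 0.11 (adjusted p = 0.0146), from 0.06 ± 0.20 to 1.31 ± 0.20, and probe 14331 rose by 1.64 ± 0.19 (adjusted p = 0.0460), from -3.33 ± 0.45 to -1.68 ± 0.50. The 4 high and the 4 low lung arrays did not overlap at any of the 5, which chance gives for 2.86% of orderings, and the probes had been picked by their difference. The difference kept its direction among the Cy5 arrays and among the Cy3 arrays taken alone. Groups without overlap must do so, and this is no further evidence. Probe 8267 passed among the Cy5 arrays, and no other of the 5 passed in either. Probe 14331 did not pass without a dye term (adjusted p = 0.166), nor probe 14467 with arrays scaled to one spread (adjusted p = 0.0596). Read as channel 2 over channel 1, the lung values gave 0 calls. Leaving out 1 array left 1 call (without high burden lung replicate 2 or low burden lung replicate 4) to 8 calls (without low burden lung replicate 3), and of these 8 fits, probe 8267 passed in 8, probes 4956 and 7068 in 4 and probes 14331 and 14467 in 1. In 1 fit over all 16 arrays, probes 8267 (adjusted p = 0.0893) and 4956 (adjusted p = 0.133) did not pass.

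**Figure D3:**
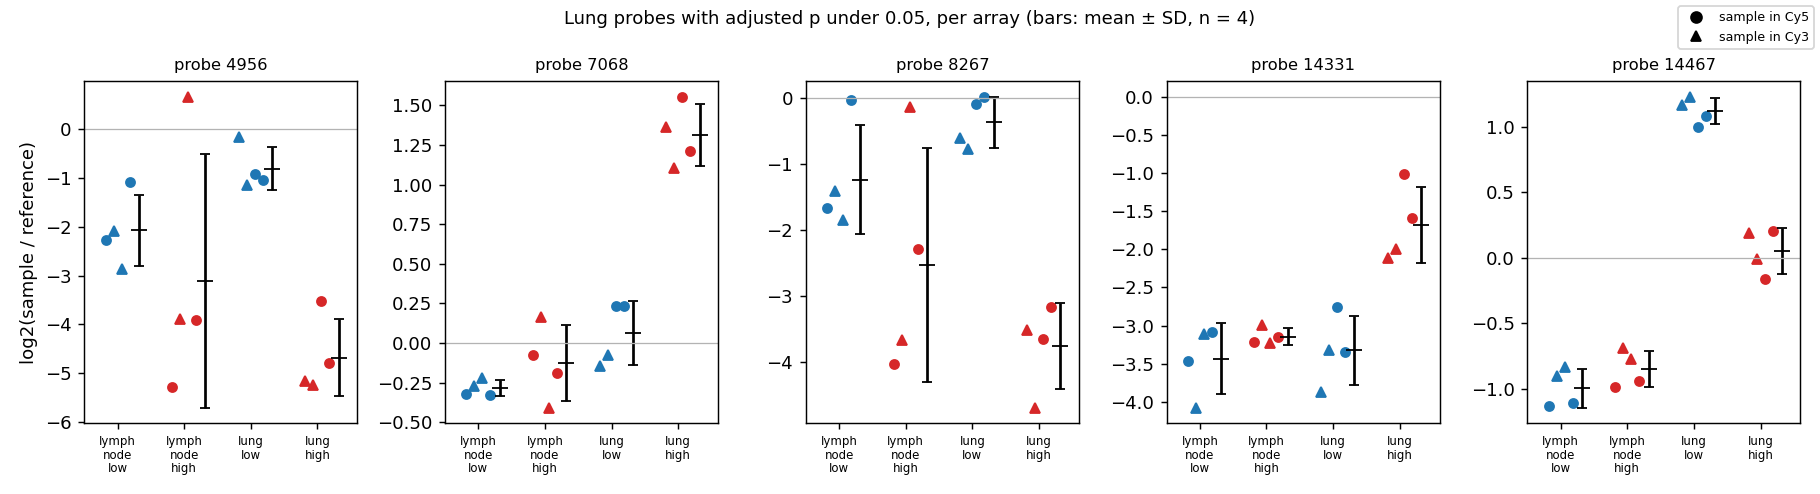
Log2 ratio of sample over reference (y axis) of the 5 probes that differed between high and low burden lungs, per array and group (x axis). Circles are arrays with the sample in Cy5, triangles those with it in Cy3, and bars give the mean and SD of 4 arrays. The lung groups do not overlap in any panel, while in lymph node high burden replicate 3 lies at 0.66 for probe 4956, apart from the other high burden arrays.

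No named gene passed the threshold in lung: 8 of 178 named probes had an unadjusted p under 0.05, and the smallest adjusted p of a named probe was 0.444. That value belonged to MADCAM1, with a high minus low difference of 0.45 ± 0.12 (SE). Its SD was 0.44 in low and 0.50 in high burden lungs, about as large as the difference, and the SE is that left after the dye term. PSMB8 had 0.43 ± 0.15 (adjusted p = 0.577), and 0.30 ± 0.13 without the 1 low burden array on which its spots were misplaced. The adipocyte protein ADIG had 0.40 ± 0.12, the oestrogen sulfotransferase SULT1E1 0.30 ± 0.12 and the complement regulator CD46 0.28 ± 0.14. GLRB, MC1R, IL1A, SPRP and UOX had differences between 0.17 and 0.24, and the spots of GLRB (0.07 after the blocks were moved back) and IL1A were misplaced on 2 and 1 of these arrays. TYROBP had -0.56 ± 0.18 (adjusted p = 0.569), with 0.68 ± 0.35 (SD, n = 4) in low and 0.12 ± 0.20 in high burden lungs. The antigen-presenting molecule CD1.1 had -0.41 ± 0.20, the lysosomal membrane protein LAMP1 -0.60 ± 0.35, the protegrin NPG4 -0.30 ± 0.18 and SSTR2 -0.28 ± 0.11. KLK1 had -0.41 ± 0.14, with 2 low burden arrays misplaced there, and -0.28 after the blocks were moved back. PAG6, misplaced on 1 array, IL21, CSN1S1 and GAD1 had differences between -0.23 and -0.18. SIGLEC1, misplaced on 1 array, had -0.01 ± 0.12, and 0.07 ± 0.11 without that block. With 1 array left out at a time, the values of CD1.1, NPG4, LAMP1 and CSN1S1 came up to -0.22, -0.11, -0.36 and -0.13, and those of CD46, MC1R, IL1A, SPRP and UOX went down to 0.17, 0.12, 0.11, 0.13 and 0.12. An unadjusted p under 0.05 was reached by 1644 probes over the whole array, where 1037 would be expected by chance. Such an excess also arose without the burden groups: at an unadjusted p under 0.01 the real split had 401 probes and another split of the lung arrays 525.

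In the test of the burden effect between the tissues, 1 probe passed. Probe 14467 had a lung effect 1.22 ± 0.13 (SE) below the lymph node effect (log2 difference -1.22, adjusted p = 0.00279 in limma's test over all 16 arrays). In lymph node its high minus low difference was 0.15 ± 0.07. The lung Cy3 arrays carry different reference names for low and high burden, and the lymph node arrays carry 1. A difference between references would thus enter this tissue difference. On the Cy5 lung arrays alone, which share 1 reference name, the lung difference of probe 14467 was -1.02 ± 0.17 (adjusted p = 0.426 in limma's test). Read as channel 2 over channel 1, the difference of probe 14467 was 0.0341 and 0 probes passed, and of 100 splits of the arrays, the real one included, 9 gave at least 1 call. The other 4 probes called in lung had adjusted p between 0.168 and 0.738 for the difference between tissues, so a difference was not shown for them. No named probe passed, and the smallest adjusted p among them was 0.590, that of SSTR2 (-0.43 ± 0.13). The other named genes with the smallest p were PSMB8 at 0.69 ± 0.31, ADIG at 0.47 ± 0.22, IL1A at 0.31 ± 0.15, PGLYRP1 at 0.77 ± 0.40 and LTA at 0.26 ± 0.16, and, on the negative side, GAD1 at -0.31 ± 0.14, NPG4 at -0.47 ± 0.21, CD1.1 at -0.56 ± 0.26 and SMCP at -0.35 ± 0.17. With the misplaced blocks left out, PSMB8 had 0.32, and with them moved back IL1A had 0.15. Moved back, the high minus low difference of PSMB8 was 0.06 in lymph node (-0.26 as deposited) and 0.32 in lung (0.43 as deposited). PGLYRP1 had 0.38 without high burden lymph node replicate 1, and PSMB8, ADIG, LTA, NPG4, CD1.1 and SMCP went to 0.44, 0.29, 0.14, -0.275, -0.36 and -0.21 with 1 array left out. At an unadjusted p under 0.05 there were 1390 probes, where 1037 would be expected by chance. At an unadjusted p under 0.01 the real split had 324 probes and another split 552.

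Gene lists fixed beforehand could be examined only in part, since 23 of their 760 genes were among the named ones. Of 29 lists, 6 had at least 2 measured members and were tested with camera, 10 had 1 and 13 had none. In lung, both measured members of the list for MHC class I and antigen processing had positive differences, PSMB8 at 0.43 and PSME1 at 0.11, with an adjusted p of 0.0728 and, with an estimated correlation, an adjusted p of 0.282. Both members of the heat shock and immediate early list had negative differences, JUN at -0.51 and KLF4 at -0.32 (adjusted p = 0.141). SIGLEC1 at -0.01 and TYROBP at -0.56 made up the monocyte and macrophage list (adjusted p = 0.167). Adjusted over the list alone, 1 gene passed in each of 2 lung lists, PSMB8 at 0.0329 and TYROBP at 0.0286, and over all probes none did. The unadjusted limma p of PSMB8 rose from 0.0170 to 0.0474 with its misplaced block left out, and was 0.0198 with it moved back. The adjustment over the list alone was not repeated in these settings. At an unadjusted camera p under 0.05 there were 2 lists in lung and 1 in lymph node. The neutrophil genes (NPG4, PGLYRP1, PR39), the inflammatory cytokines (IL17A, IL1A, LTA) and the erythrocyte and platelet genes (HBE1, ITGA2B) had adjusted p of 0.317, 0.238 and 0.783 in lung. In lymph node the 6 lists had adjusted p between 0.263 and 0.660, and no gene passed adjusted over the list alone. The lung lists measured by PSMB8 and PSME1 and by JUN and KLF4 passed camera (adjusted p = 0.0399 for both) after the misplaced blocks were moved back. This setting was chosen after seeing the data. With an estimated correlation in that setting the adjusted p = 0.244 for both, JUN had -0.55 and PSMB8 0.32. Over all settings tried, the adjusted p lay between 0.0376 and 0.956 for the list of PSMB8 and PSME1. For that of JUN and KLF4 it lay between 0.00168 and 0.566.

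**Figure D4:**
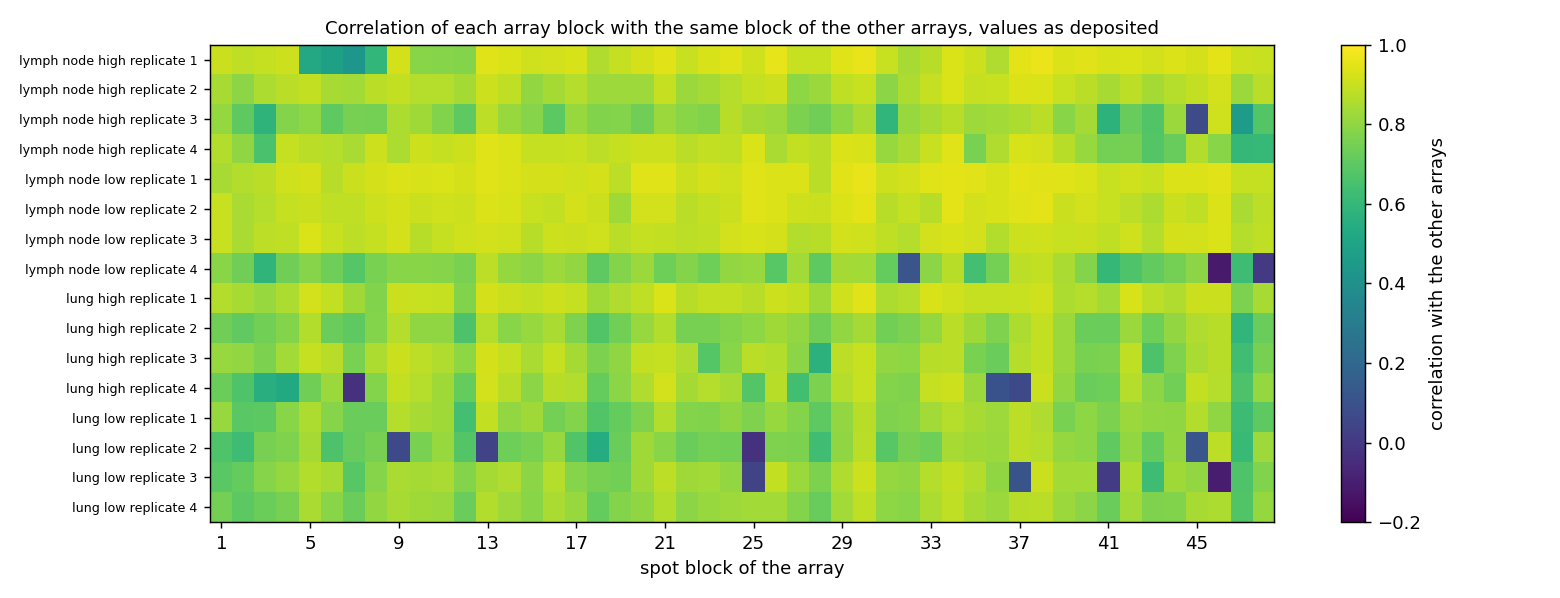
Correlation of each of the 48 spot blocks (x axis) of each of the 16 arrays (y axis) with the same block of the other arrays, values as deposited. The 15 dark fields, at correlations between -0.11 and 0.12, are the misplaced blocks, and the fields of high burden lymph node replicate 1 in blocks 5 to 8 are low as well.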

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

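The tests on the direction of the ratio and on the splits balanced over dye were chosen only after the result was seen, while those on all splits of the arrays and on the reference names were written before it. A sample was singled out when its gap to the nearest of the 4 arrays of its group exceeded 0.829 of the group's range. This happened in 8 of 132 groups of values examined, and chance does so in about 1 of 20.

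In lymph node high burden replicate 1, PGLYRP1 lay at -1.38 against 0.13 to 0.29 on the other arrays of its group, and B3GNT5 at -1.45 against -0.06 to 0.15. Their spots are in blocks 12 and 11 of that array, each of which holds 21 spots more than 0.8 below the other arrays. ADIG lay at 0.40 in lymph node low burden replicate 4 against -0.40 to -0.31. SPRP lay at 0.58 in lung low burden replicate 1 against 0.06 to 0.10, and at 0.66 in lung high burden replicate 2 against 0.31 to 0.34. CD1.1 lay at 0.54 in lung low burden replicate 1 against -0.20 to -0.08, and at -0.82 in lung high burden replicate 2 against -0.25 to -0.23. Without lung low burden replicate 1 the lung difference of CD1.1 was -0.22 and without lung high burden replicate 2 it was -0.23. The median correlation of lymph node low burden replicate 4 with the other lymph node arrays was 0.654, against 0.804 to 0.827 for the rest of its group. High burden replicate 3, not singled out by the rule, was nearly as low at 0.663, against 0.776 to 0.804 in its group. Low burden replicate 4 holds 3 misplaced blocks and print positions that differ from those of 6 lymph node arrays. Their share in its low correlation was not tested.

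The burden effect at probe 14467 differed between the tissues, with a lung minus lymph node difference of -1.22 on the log2 scale. Of 100 splits within both tissues, the real one included, 9 gave at least 1 such probe, and the highest of the others gave 4, so chance is not excluded as an explanation of the count. Different references behind the names of the lung Cy3 arrays are not excluded for this difference either.

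The 5 lung calls were weighed against 3 technical explanations. Of the 34 splits of the 8 lung arrays that can be fitted, only 1, the real split, gave as many, and the highest of the others gave 1, but of these only 18 balance the dyes as the real one does (1 gave as many, highest other 0), too few for a share under 0.05. A deposited ratio of channel 2 over channel 1, under which there are 0 calls, is argued against: the lymph node minus lung difference would then turn between dye orientations, and it correlated at r = 0.604 between Cy5 and Cy3 arrays whose lymph node arrays belong to different print sets. Different reference pools behind the names of the Cy3 arrays can be judged for probe 8267 only. Among the Cy5 arrays, which share 1 reference name, the median effect was 113.6% of that among the Cy3 arrays. Probe by probe it was 69.8% to 113.6% (median 92.1%). The 5 probes were picked from a fit that held these Cy5 arrays and favours like effects in both orientations, so these shares do not decide it. Probe 8267 passed limma's test on the Cy5 arrays alone (adjusted p = 0.0207, 2 arrays per group), which argues against different pools for that probe. No other of the 5 passed there. The wider excess of lung probes at an unadjusted p under 0.01 is another matter, since 3 of 34 splits, the real one included, gave at least its 401, and the highest other gave 525. In lymph node the splits say nothing on the 0 calls, since each of 34 has at least 0 (highest other 2). There, 16 of 34 splits, the real one included, had at least its 131 probes at an unadjusted p under 0.01 (highest other 479). None of the 5 probes lies in a misplaced block, and a biological difference that goes with the burden groups without following from the virus, such as breeding, stays open and was not tested.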

How the results depend on the processing

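The tests with misplaced blocks, print positions and print set, and those with an estimated correlation in other settings, were chosen only after the data were seen, and all other settings before. In lymph node, 0 probes passed in limma's test under each setting tried (857 at an unadjusted p under 0.05), except that an unadjusted p under 0.01 gave 131, and each leave-one-array-out fit gave 0. The 5 lung calls were 4 without a dye term (without probe 14331), 5 with centring, array weights or robust moderation, 5 with scaling (4 shared, without probe 14467), 4 in 1 fit over all arrays (3 shared, without probes 8267 and 4956), 7 with the misplaced blocks left out or moved back (5 shared) and 6 at an adjusted p of 0.10. They became 0 read as channel 2 over channel 1, 8 with quantile normalization, 1 on the Cy5 arrays alone (probe 8267) and 0 on the Cy3 arrays alone, where each group has 2 arrays. Without the less variable part of the probes (those with a spread below the median) there were 20, at an unadjusted p under 0.01 there were 401, and over named genes alone 0, since none of the 5 probes is named. Leaving out 1 array gave 1 to 8: 1 without high replicate 2 or low replicate 4, 2 without low replicate 1 or high replicate 3, 3 without high replicate 4, 4 without high replicate 1, 5 without low replicate 2 and 8 without low replicate 3. For the difference between tissues the 1 call became 0 under the other reading, 324 at an unadjusted p under 0.01 and 0 over named genes, and leaving out 1 array gave 1 to 2 (2 without lymph node high replicate 2, 3 or 4). Of the 6 lists 0 passed in lymph node under each setting, also with 1 array left out (0 to 0). In lung 1 passed without a dye term (the list of PSMB8 and PSME1, adjusted p = 0.0493). There were 2 with the misplaced blocks moved back, and 0 to 2 with 1 array left out (2 without low replicate 3). With an estimated correlation none of these passed: adjusted p = 0.274 without a dye term and 0.244 for both lists moved back. Without low replicate 3 it was 0.194 (PSMB8 and PSME1) and 0.122 (JUN and KLF4). Missing-value settings changed nothing, since no value is missing. KLK1 could not be tested in lung with the blocks left out. The cause of these changes was not tested beyond what the numbers of probes or arrays tested give.

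The 5 called lung probes kept direction and side of the threshold in 52 values and direction only in 13. With 1 array left out they kept both in 18 and direction only in 22, so most calls were then lost. Their lung groups do not overlap, so their direction could not turn when arrays were left out. Probe 14467 in the tissue difference kept both in 10 values and, with 1 array left out, in 16. Named genes kept both in 678 values and with 1 array left out in 493. None of them had passed, so keeping their side meant staying short of the threshold. All but SIGLEC1 were picked by a small p in these arrays, which favours keeping the direction. The counts outside leaving out arrays include the missing-value settings, which repeat the main fit. Under the reading as channel 2 over channel 1, 24 named values kept their direction. Those reversed in lymph node were CACNB4 (-0.0691), CYP7A1 (-0.39), CRSP3 (-0.12), UOX (-0.20), GLRB (-0.12), TYROBP (0.22), LTA (0.0112), KLK1 (0.25), FOLR1 (0.0099), MYOCD (0.14) and SIGLEC1 (-0.0418). In lung they were ADIG (-0.19), PSMB8 (-0.0084), CD46 (-0.30), MC1R (-0.25), IL1A (-0.0853), KLK1 (0.0594), SSTR2 (0.11), IL21 (0.0765), CD1.1 (0.35), NPG4 (0.26) and probes 4956 (0.69), 7068 (-0.0982), 8267 (0.0176) and 14467 (0.0442). In the tissue difference they were PSMB8 (-0.24), LTA (-0.0143), SSTR2 (0.0854), GAD1 (0.13), NPG4 (0.41), CD1.1 (0.29), SMCP (0.0551) and probe 14467 (0.0341). On the Cy5 arrays alone, CYP7A1 (-0.0025), KLK1 (0.0227), MYOCD (0.0097) and SIGLEC1 (-0.0201) reversed in lymph node and CD46 (-0.0144) and MC1R (-0.0043) in lung. On the Cy3 arrays alone CA11 in lymph node (0.0012) and SIGLEC1 in lung (0.17) reversed. SIGLEC1 also reversed in lung with the misplaced blocks left out (0.0736), and with 1 array left out ranged from -0.0019 to 0.0446 in lymph node and from -0.0704 to 0.0736 in lung. The cause was not tested. Signal over background was not used here, so its limits on dim probes are unknown.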

Other observations

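The fit of tissue levels, the liver list and the print positions were chosen only after the data had been seen. Lymph node and lung differed at 3393 of 20736 probes (limma, adjusted p under 0.05), with 8 named probes higher and 21 lower in lymph node, although the reference carries different labels in the 2 tissues, and a difference between references would enter these values. The count holds 149 of 1152 probes at print positions that do not match between 6 lymph node arrays and the other 2. For 768 of these probes a mismatch with the lung arrays was seen as well, and for the others it was not computed. Without these positions the count was 3306 of 19584, with 8 named probes higher and 23 lower. Named genes higher in lymph node were TLR10 by 0.80 ± 0.11 (SE), PSMB8 by 0.60 ± 0.16, CD1.1 by 0.51 ± 0.13, PSME1 by 0.43 ± 0.07, MADCAM1 by 0.34 ± 0.09 and the T cell cytokine IL21 by 0.23 ± 0.06. HYAL3 and PIK3C3 were also higher in lymph node. With the misplaced blocks left out, PSMB8 differed by 0.66 and CD1.1 by 0.57, and 9 named probes were higher and 20 lower. RPN2 then passed (0.79, adjusted p = 0.00195, against 0.53 and 0.0613 with them), as did SCGB1D1 and CCR9, both lower in lymph node (adjusted p = 0.0479 and 0.0483, against 0.0508 and 0.0515). LTA and ITM2A no longer passed (adjusted p = 0.0974 and 0.0501), and ITGB1 could not be tested.

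Of the 21 named probes lower in lymph node than in lung, PLA2G1B had the largest difference (-1.61 ± 0.20, SE). It was followed by MBL2, a collectin (-1.33 ± 0.14), monoamine oxidase A (MAOA, -1.15 ± 0.20) and the caveolar protein CAV1 of endothelial and alveolar type I cells (-1.12 ± 0.23). The immediate early gene JUN (-0.82 ± 0.20), S100A11 (-0.68 ± 0.10), KLF4 (-0.53 ± 0.17), TSPO (-0.47 ± 0.14) and the leptin receptor LEPR (-0.40 ± 0.08) were also lower in lymph node. CAV1 was read from misplaced spots on 1 lymph node array and JUN on 2 lung arrays, and without them the differences were -1.36 and -1.10. CYBA (0.60 in lymph node and 0.63 in lung against the reference), a subunit of the phagocyte NADPH oxidase, and TYROBP (0.50 and 0.40) had tissue differences of -0.03 ± 0.07 and 0.10 ± 0.13 that did not pass the test.

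The liver genes CRP, PROC, UOX, CYP7A1, CYP8B1, MBL2 and PGLYRP2 had a lower median than the other named genes in both tissues, with -1.02 against 0.01 in lymph node and -0.22 against 0.01 in lung. A probe-specific dye bias is argued against for the mean over the 7 genes only, with the ratio read as sample over reference. This mean was below 0 in both orientations of both tissues, and the highest of the 4 means was -0.65. In lung CRP (-2.48) and PROC (-2.05) weigh most in it, and no single probe was judged by orientation. The labels give the reference the tissue of its sample. A candidate explanation is a reference that also holds RNA of other tissues, and the larger of the 2 permutation p-values against the other 171 named probes was 0.00397. The list was made from genes already seen to be low, so this p is not independent evidence. In lung, MBL2 lay at 0.31 and CYP8B1 at 0.08, above the median of the other named genes, and CRP at -2.48. INHA, which is not on the list, lay at -1.50 in lymph node and -1.29 in lung. It was below UOX in both tissues (-1.44 and -0.69), so low levels were not particular to the list. No biological explanation was tested.

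The 15 array blocks without correlation to the other arrays had correlations between -0.11 and 0.12 in place, while the other 753 blocks had at least 0.43. A local hybridisation defect is argued against, since the median correlation after moving the blocks back was 0.768. A spot grid placed 1 or 2 spots off may account for them: the lowest correlation after moving back was 0.599. The blocks are 13 shifted by 1 spot and 2 by 2 spots. They lie on lung low burden replicates 2 and 3 (4 each), lung high burden replicate 4 (3), lymph node low burden replicate 4 (3) and lymph node high burden replicate 3 (1). At CAV1 the lymph node high minus low difference was 0.07 ± 0.39 (SE) as deposited, 0.56 ± 0.10 with the misplaced block left out and 0.02 ± 0.43 with it moved back, none of which passed the adjusted threshold.

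In 2 neighbouring runs of 8 positions in each block, 6 lymph node arrays matched the other 2 lymph node arrays only when the runs were exchanged. Between these 2 sets, the median correlation of a position was -0.01 in place and 0.793 exchanged, over 768 probes. In place, pairs of 1 of the 6 and 1 of the other 10 arrays, lung included, had r of at most 0.059 over these runs. Pairs among the 10 had at least 0.377. The exchange was not computed against the lung arrays. At the last 8 positions of each block (384 probes) the median correlation between the 6 and the 2 lymph node arrays was -0.02, and at all other positions 0.844. The lymph node arrays on the side of the lung arrays are high burden replicate 4 and low burden replicate 4. The named probes and the 5 called lung probes lie at other positions.

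In lymph node, the called lung probes 4956 and 8267 varied together over the 8 arrays, with Pearson's r = 0.927 (exact permutation p = 0.000496) and Spearman's rho = 0.952 (exact permutation p = 0.00114). Without the 2 arrays farthest from the median of probe 4956, high burden replicates 1 and 3, r was 0.914. This pair was picked after its values were seen, and 52 of 20735 probes had an r above 0.9 with probe 4956. Probe 4956 ranked 7 and probe 8267 ranked 23 of all probes by spread across the lymph node arrays.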
